A study of Mus musculus with 6 samples.

How the data were processed

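RNA from 6 fibroblast cultures was biotin-labelled and hybridised to 1-colour MouseWG-6 bead arrays, 1 array per culture, per the labels' protocols and the file headers. The labels name 3 knockout and 3 wild-type samples, and the series design states that the cultures came from 3 embryos of each genotype, so the replicates are separate cultures. Groups and replicate numbers were taken from the labels alone.

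The authors deposited 3 tables. The first holds the mean bead intensity of each probe, with the SD and the number of beads, exported with GenomeStudio version 1.6.0 without normalization and without an error model, per the file headers. Its detection values are a fraction from 0 to 1, per the file headers, in which 1 means detected; 1 minus this fraction was used as the detection p. The deposited normalized table holds a score on a log-like scale made with lumi, per the submitters' processing notes; its transformation, log base and method are not given in the sources used here. Against log2 intensity its slope was 0.960 between 9 and 11 and 0.571 between 6 and 7, each array kept the rank order of its intensities, and the array medians were all 7.13. The third deposited table, whose values were read as log2 from that slope, held the same 45281 sets of values under other probe names. The values are thus single-array levels, not ratios or centred values, so that direction is settled, and the exact scale below bright signals stays unknown. The intensity table was used for all main results, and 24 of its 48 per-array columns (lowest and highest signal, array number and SD over arrays) were not used.

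Intensities were background-corrected and quantile-normalized with neqc of limma version 3.58.1 in R version 4.3.3, which estimates background from the detection p, adds an offset of 16 and takes log2. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, 18221 of 45281. Median intensity per array lay between 88.7 and 97.9, and the median number of beads per probe was 43 on each array. Fold changes of dim genes depend on the background correction, and were smaller without it (Atmin -1.47 in place of -1.99).

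Array names were updated through a reference gene table of assembly GRCm38.p6, which was used for names and neighbours only. Of all probes 27400 matched a current symbol, 940 a gene ID and 8300 a synonym held by a single gene, 80.9% together; 8641 stayed unnamed. Of the detected probes 90.6% were named, and for each gene the detected probe with the highest mean over the 6 arrays was kept, giving 10700 genes. The 1720 detected probes without a name entered the test of single probes alone.

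Genes were tested with lmFit and eBayes of limma on log2 values, knockout minus wild type, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors of single genes are the moderated ones of that model. Those of list means are ordinary pooled ones of the per-culture means, without moderation. Where a probe was not detected on any array of a group, the fold is a bound: the mean of the other group against the mean of, per array, the higher of the probe's own value and the lowest value among detected probes. Adjusted p of gene lists are Benjamini-Hochberg values over the lists.

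The 33 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. They comprise 22 pathway lists, 9 lists of other cell types, 1 of neighbours of Atmin and 1 of sex-linked genes; 32 had at least 3 tested genes. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, and members were also adjusted over the list alone. Genes named are Atmin, Dynll1 and Dynll2; among genes past the threshold whose groups do not overlap the 10 with the largest rise and the 10 with the largest fall, each direction filled up to 5 with the smallest unadjusted p; per list up to 3 members past the threshold or else the member with the smallest p; and genes needed for the sex and neighbourhood checks. Further members named within a list were chosen after their values were seen.

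The procedure was tested on simulated data for this comparison, with the real means of the 10700 genes and 200 genes changed, in 20 simulations. In these simulated data it recovered 96.5% of genes changed 4-fold, 66.6% of genes changed 2-fold and 10.8% of genes changed 1.5-fold, and 4.42% of its calls were false. The real arrays differed in precision, with fitted array weights from 0.42 (knockout replicate 3) to 2.64 (knockout replicate 2). Whether the simulated rates hold for them was not tested. Alternatives covered background correction, normalization, the filter on dim probes, the rule for several probes, the variance model, the replicate number as a block, each array left out, the threshold and the set test. Added after the data were seen were culture sex as a covariate, the array's own target names as genes, and leaving out the XX culture and knockout replicate 3 together. No 2 arrays held the same values. An exact permutation test of 3 against 3 cannot go below p = 0.10, so single genes were not tested that way.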

Results

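Gene expression was measured in primary mouse embryonic fibroblasts, the adherent connective-tissue cells that grow out of a minced embryo, taken at embryonic day 12.5 and passaged once before RNA was isolated. Of the 6 cultures, 3 came from Asciz knockout embryos and 3 from wild-type embryos on a C57BL/6 background. Asciz is the older name of Atmin, which encodes a zinc-finger transcription factor, and the comparison asked which transcripts differ when it is missing. Each culture was hybridised to 1 whole-genome bead array with 45281 probes, and between 17580 and 18794 probes per array gave a signal above background. The number of arrays, 3 per genotype, limited the precision. Xist, the RNA that coats the inactive X chromosome, was detected only in wild-type replicate 1, where its 4 probes with any detection averaged 8.20 on the log2 scale against 4.32 to 4.37 on the other 5 arrays. The Y-linked genes Ddx3y and Eif2s3y averaged 4.86 in that culture and 9.25 to 9.58 in the others, so 1 wild-type culture had an XX pattern and the remaining 5 cultures an XY pattern. Knockout replicate 3 stood farthest from the rest, with a mean correlation of 0.979 to the other arrays across genes, against 0.985 to 0.989 for the other 5.

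Atmin, the targeted gene, fell in the knockout cultures. Its brightest probe averaged 8.78 ± 0.08 in wild type and 6.79 ± 0.27 in knockout cultures (normalized log2 intensity, mean ± SD, n = 3 each), a log2 fold change of -1.99 (SE 0.16, 95% confidence interval -2.36 to -1.63, adjusted p = 0.00896 by limma). A second bright probe gave -1.95, with 7.94 ± 0.09 against 5.99 ± 0.19 (n = 3 each). The third Atmin probe lay near background, was detected on 3 of the 6 arrays and gave 0.11. The bright probes stayed above background on all 3 knockout arrays. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so the remaining signal says nothing about residual full-length transcript. The call was lost when any 1 wild-type array was left out, with adjusted p between 0.0810 and 0.108 and log2 fold changes between -2.03 and -1.95. It was also lost when the dim probe was averaged in (-1.28, adjusted p = 0.0686), within a range of 0.00161 to 0.339 over its alternatives. In the submitters' normalized values, whose scale is compressed for dim probes, Atmin stood at -1.20.

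Dynll1 fell in the knockout cultures. It encodes LC8, a small dynein light chain and binding hub, and ASCIZ is known to bind and activate its promoter. The probe named DYNLL1 averaged 13.13 ± 0.07 in wild type and 11.24 ± 0.02 in knockout cultures (n = 3 each), a log2 fold change of -1.89 (SE 0.10, 95% confidence interval -2.14 to -1.65, adjusted p = 0.00181 by limma). In unnormalized brightness this was 9054 ± 1087 against 2307 ± 413 intensity units (SD, n = 3 each). The second probe, carried under the older name DNCLC1, gave -2.31, with 9.97 ± 0.13 against 7.66 ± 0.17 (n = 3 each). Dynll2, the paralogue that encodes a nearly identical light chain, averaged 8.70 ± 0.17 in wild type and 8.77 ± 0.14 in knockout cultures (n = 3 each), a difference of 0.07 (SE 0.14, adjusted p = 0.920 by limma) that turned to -0.16 when arrays were scaled to a common median, a scaling that moved the median of all genes by -0.18. Dynll1 stayed past the threshold under each of its 22 alternatives, with log2 fold changes between -2.10 and -1.85 and adjusted p between 7.81e-06 and 0.0433.

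**Figure D1:**
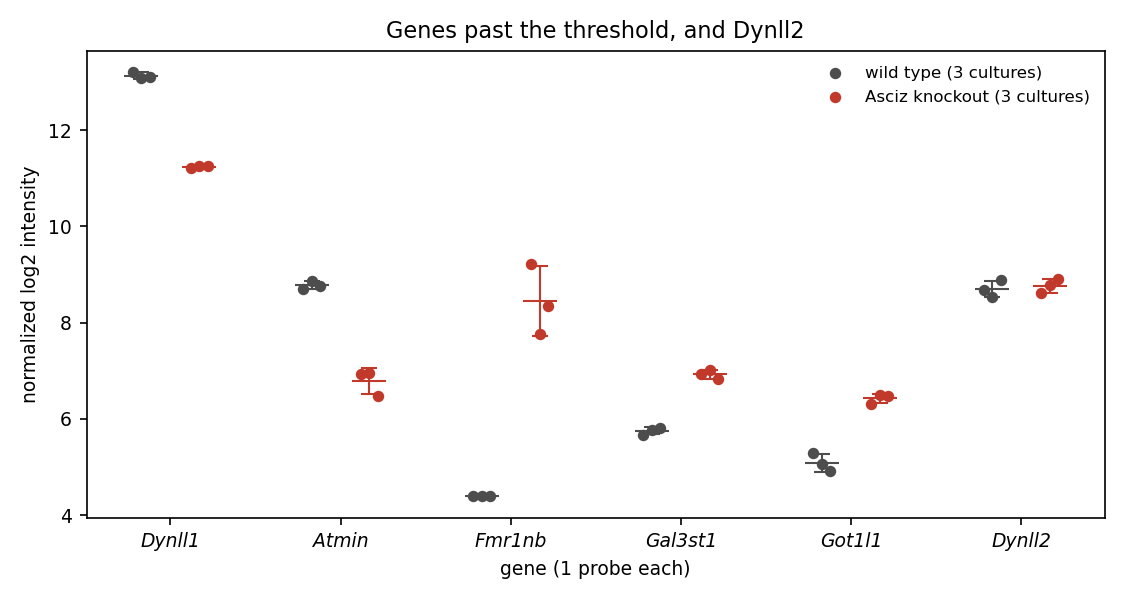
Normalized log2 intensity (vertical axis) of the 5 genes past the threshold and of Dynll2 (horizontal axis) in 3 wild-type and 3 knockout cultures; each point is 1 culture, the horizontal dash is the mean and the bar is the SD. Dynll1 and Atmin lay lower in all 3 knockout cultures, Fmr1nb, Gal3st1 and Got1l1 lay higher, and the Dynll2 values overlapped.

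Across 10700 genes, 5 passed an adjusted p of 0.05, all of them by at least 1.5-fold: Dynll1 and Atmin fell, and Fmr1nb, Gal3st1 and Got1l1 rose. Fmr1nb, an X-linked neighbour of Fmr1 known for expression in testis, was not well above background on any wild-type array and was detected on all 3 knockout arrays, at least 12.6-fold higher (adjusted p = 0.00896 by limma). That bound holds for the background correction used: the fitted difference of 4.05 was 2.65 with an offset of 50 and no negative controls, and 1.64 in the submitters' normalized values. Its knockout values spread widely, at 8.45 ± 0.73 (n = 3), and a second Fmr1nb probe was detected on 2 knockout arrays and no wild-type array, at least 1.25-fold higher, while the remaining probe was not well above background on any array. Gal3st1, the sulfotransferase that makes sulfatide and seminolipid, rose by 1.17 (SE 0.11, adjusted p = 0.0250), from 5.75 ± 0.07 to 6.93 ± 0.10 (n = 3 each). Got1l1, a relative of cytosolic aspartate aminotransferase, rose by 1.34 (SE 0.13, adjusted p = 0.0292), from 5.09 ± 0.19 to 6.43 ± 0.10 (n = 3 each). Leaving out wild-type replicate 1, the XX culture, left Dynll1 alone, as did leaving out wild-type replicate 3. Without wild-type replicate 2 Dynll1 and Sprr2k passed, the latter not among the original 5, and without knockout replicate 2 Dynll1, Atmin and Fmr1nb. Median scaling called 4 genes, 1 higher and 3 lower, of which 3 were among the original 5 and the other was Lyz1. Without the XX culture and knockout replicate 3 together 5 passed, of which 2 were among the original 5. The others were Erdr1 (3.46) and the macrophage list members Lyz1 (-2.34) and Fcer1g (-1.81). Minar2, not among the original 5, passed without knockout replicate 1 (1.37) and with array weights (1.52). Got1l1 lost its call whichever single array was left out (adjusted p from 0.0810 to 0.220), and Gal3st1 kept it without knockout replicate 3 alone (adjusted p from 0.0436 to 0.226). Gal3st1 (0.42) and Got1l1 (0.36) were smaller in the submitters' normalized values, where neither they nor Fmr1nb passed, with adjusted p over their alternatives from 0.00242 to 0.469 for Fmr1nb, from 0.00421 to 0.277 for Gal3st1 and from 0.0116 to 0.377 for Got1l1.

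**Figure D2:**
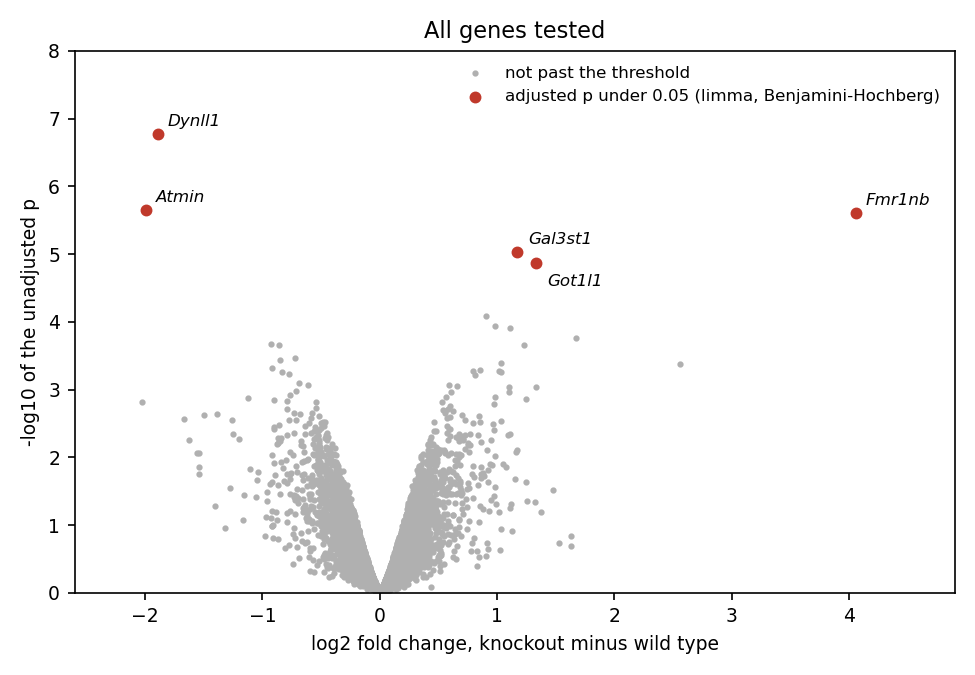
Log2 fold change, knockout minus wild type (horizontal axis), against -log10 of the unadjusted p (vertical axis) for the 10700 genes tested, 1 point per gene. The 5 genes with an adjusted p under 0.05 are filled and named; Dynll1 has the smallest p and Fmr1nb the largest fold change.

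No other gene passed. The next smallest adjusted p was that of Gstp2, a pi-class glutathione S-transferase, at 0.147 (log2 fold change 0.91, SE 0.12); it was detected on 1 wild-type and all 3 knockout arrays. Rps4l, which resembles the ribosomal protein S4 genes, had 0.98 (SE 0.14, adjusted p = 0.165). Among genes lower in the knockout cultures that did not pass, Ms4a7, a membrane protein of macrophages, was not well above background on any knockout array and lay at least 1.57-fold lower (adjusted p = 0.199). Gm4788, detected on 1 knockout array, had -0.86 (SE 0.13, adjusted p = 0.199) and Ltbp2, a latent TGF-beta binding protein family member of the matrix, had -0.73 (SE 0.12, adjusted p = 0.266). Some of these genes passed under alternatives. Rps4l did so with a trended, robust variance model (adjusted p = 0.0378 by limma) and with array weights (adjusted p = 0.0284). Gstp2 and Ms4a7 did so with array weights (adjusted p = 0.0460 each). At an unadjusted p under 0.05 there were 854 genes, 417 higher and 437 lower, where chance alone gives 535 on average. Dividing the 6 arrays in ways that mix the genotypes gave between 173 and 1115 such genes. The excess over 535 therefore does not by itself show a genotype effect. The 3 knockout values lay all above or all below the 3 wild-type values for 1555 genes, or 14.5%, where chance gives 10% on average. That share was not computed for other divisions of the arrays.

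The fixed gene lists were tested with camera for a shift against all other genes, and 6 of the 32 testable lists passed: 2 higher and 4 lower in the knockout cultures (7 higher and 5 lower under median scaling). None of the 6 passed with an estimated correlation between genes, so each is given with both values. That setting also leaves camera far fewer degrees of freedom, and it called 0 lists for each of the 10 splits of the arrays into 3 and 3. Oxidative phosphorylation lost its call there although its genes correlated within genotypes at a mean of 0.0087, below the preset 0.01. Failing that setting is therefore no evidence that a list is unchanged. The dynein and dynactin list held 20 tested genes, of which Dynll1 alone passed, both over all genes and adjusted over the list alone, and the list did not shift (adjusted p = 0.764). Fry's directional test called that list and no other, at an adjusted p of 0.0473, and fry's mixed test likewise called it alone.

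Markers of 2 cell types other than fibroblasts stood apart, in opposite directions. All 17 tested skeletal muscle markers were higher in the knockout cultures, with a median of 0.70. The embryonic fast and slow muscle proteins Mylpf (1.11, SE 0.28), Tnnt1 (1.03, SE 0.24) and Chrna1, a subunit of the muscle acetylcholine receptor (1.09, SE 0.28), were among the 13 that passed adjusted over the list alone, and 0 passed over all genes. Actc1, the cardiac actin also made in embryonic muscle, had the smallest p (0.70, SE 0.16, adjusted p = 0.439 over all genes). Camera gave the list an adjusted p of 3.55e-14, and an adjusted p = 0.519 with an estimated correlation. All 9 tested macrophage and leukocyte markers were lower, with a median of -1.12. Of these, 7 passed adjusted over the list alone and 0 over all genes, among them the lysozymes Lyz1 (-1.67, SE 0.38) and Lyz2 (-1.50, SE 0.34), the complement component C1qb (-1.26, SE 0.29, detected on 1 knockout array) and Laptm5 (-1.12, SE 0.23, adjusted p = 0.382 over all genes). Among the alternatives, Lyz1 passed over all genes under median scaling, and Lyz1 and Fcer1g did without the XX culture and knockout replicate 3. Camera gave an adjusted p of 1.09e-07 for this list, and an adjusted p = 0.519 with an estimated correlation. Cd14 (-0.13, SE 0.18) and Mrc1 (-0.05, SE 0.16, detected on 2 wild-type and 1 knockout arrays) did not pass by either adjustment. In the submitters' normalized values the mean shifts were smaller, 0.41 for skeletal muscle and -0.40 for macrophage markers, against 0.68 and -0.96.

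The per-culture means did not overlap between genotypes for either list, nor for the neural and the chondrocyte and osteoblast lists. The same held for the dynein, ATM, BCL2, replication, mitosis, Hedgehog and oxidative phosphorylation lists. Chance gives such a gap in 10% of cases on average, so it does not single out the cell-type lists. The skeletal muscle markers averaged 7.09 ± 0.34 in wild type and 7.77 ± 0.20 in knockout cultures (n = 3 each), lowest at 6.74 in the XX culture. The macrophage markers averaged 6.67 ± 0.37 and 5.71 ± 0.20 (n = 3 each). Of the other cell types, neural and neural crest markers (8 tested, median 0.28), endothelial (6, 0.10), epithelial (11, 0.07), chondrocyte and osteoblast (15, -0.32), adipocyte (4, -0.45) and hepatocyte markers (3, -0.18) did not pass. In the same order the member with the smallest p was Ncam1 (0.51), Flt1 (0.63), Cdh1 (0.35), Comp (-1.63), Lpl (-0.69) and Trf (-0.66), none past the threshold over all genes. Adjusted over the list alone, 2 hepatocyte markers passed in opposite directions, Trf, detected on 2 knockout arrays, and Apoa2 (0.58), and none of the others did. Without the XX culture and knockout replicate 3, chondrocyte and osteoblast markers passed (mean -0.48 in place of -0.36, adjusted p = 0.000774 within a range of 0.000774 to 0.754 over the alternatives), as did epithelial markers (mean 0.45 in place of 0.07, adjusted p = 0.000431 within a range of 0.000431 to 0.958). Both also passed without knockout replicate 3 alone. Neural markers passed without knockout replicate 2 (adjusted p = 0.0423) and under median scaling (adjusted p = 0.0104), within a range of 0.0104 to 0.713. Adipocyte markers passed without knockout replicate 1 (mean -0.66, adjusted p = 0.0402) and with the replicate number as a block (adjusted p = 0.0405), within a range of 0.0402 to 0.896. A single erythroid marker was detected, Tfrc, so that list was not tested.

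Cell-cycle genes were slightly lower in the knockout cultures. Of 25 tested mitosis genes, 24 were below 0 with a median of -0.37, and 3 passed adjusted over the list alone against 0 over all genes: the spindle motor Kif11 (-0.69, SE 0.13), the spindle-pole protein Aspm (-0.72, SE 0.14) and the checkpoint kinase Bub1b (-0.47, SE 0.11). Of 30 genes of DNA replication and the G1/S transition, 29 were below 0 with a median of -0.24, and 0 passed by either adjustment; the helicase subunit Mcm5 had the smallest p (-0.52, SE 0.13). Camera's adjusted p was 3.66e-10 for mitosis and 1.42e-07 for replication, and for both the adjusted p = 0.519 with an estimated correlation. These lists were highest in the XX wild-type culture (9.63 and 8.84) and lowest in knockout replicate 3 (8.97 and 8.33). Without both of those cultures the mean shift was -0.17 in place of -0.33 for mitosis and -0.15 in place of -0.27 for replication. Leaving out the highest wild-type and the lowest knockout culture could only shrink these shifts, so this does not show that they depend on those cultures. Under median scaling the mean shift was -0.52 and -0.47, beside the shift of -0.18 over all genes. With the main processing the macrophage markers stood at a mean of -0.96 and the skeletal muscle markers at 0.68. Without both of those cultures these means were -1.255 and 0.459, where the values of the cultures left out again fixed the direction of the change. Under median scaling these means were -1.09 and 0.501.

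Of 23 cholesterol synthesis genes, 20 were below 0 (median -0.23, camera adjusted p = 0.00104, and adjusted p = 0.603 with an estimated correlation), and 0 passed singly by either adjustment; Idi1, the isomerase of the isoprenoid pathway, had the smallest p (-0.50, SE 0.19) and was detected on 2 knockout arrays. Of 39 oxidative phosphorylation genes, 28 were above 0, by little (median 0.07, mean 0.09), with a camera adjusted p of 0.00979, and an adjusted p = 0.519 with an estimated correlation. Median scaling, with its shift of -0.18 over all genes, moved the mean to -0.03, and camera still placed the list above the other genes (adjusted p = 0.00417). None of them passed singly by either adjustment, and the cytochrome oxidase subunit Cox7a2 had the smallest p (0.35, SE 0.12). The cholesterol call ended without knockout replicate 1 (adjusted p = 0.197) and with array weights (adjusted p = 0.229), within a range of 6.96e-06 to 0.603. The oxidative phosphorylation call ended without knockout replicate 3 (adjusted p = 0.0696), with array weights (adjusted p = 0.0684) and without the XX culture and knockout replicate 3 (adjusted p = 0.0532), within a range of 0.000528 to 0.519.

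**Figure D3:**
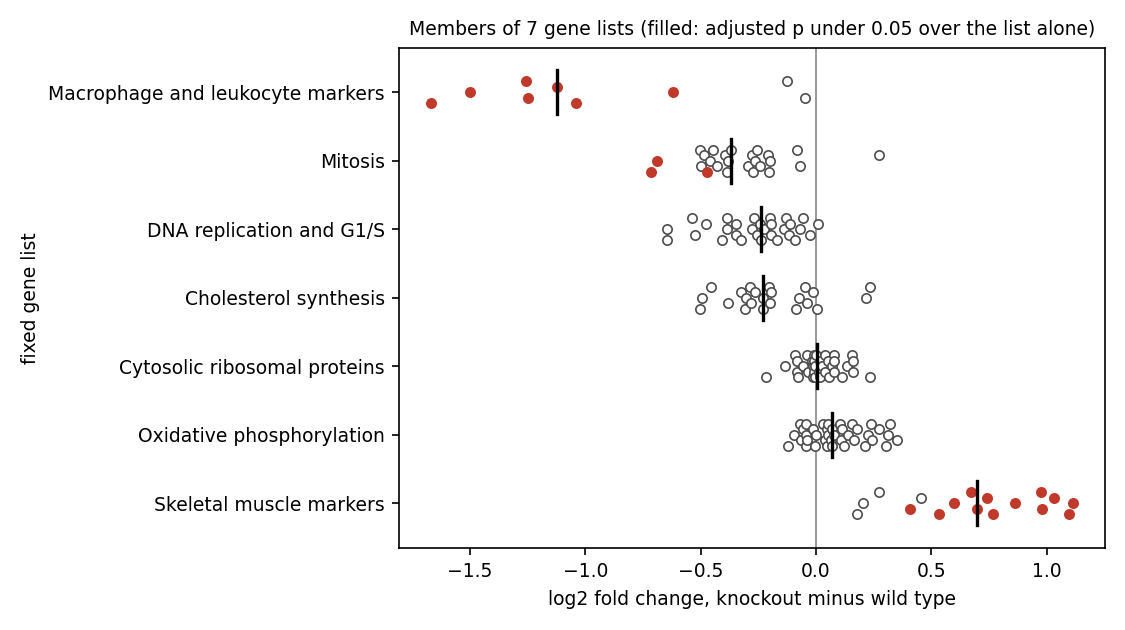
Log2 fold change, knockout minus wild type (horizontal axis), of the tested members of 7 fixed gene lists (vertical axis); each point is 1 gene, filled where it passed adjusted over the list alone, and the black bar is the list's median. Macrophage markers (median -1.12) and skeletal muscle markers (median 0.70) stood on opposite sides of 0, and cytosolic ribosomal proteins (median 0.01) centred on it; under median scaling, which shifted all genes by a median of -0.18, the mean of oxidative phosphorylation genes was -0.03 in place of 0.09 and still above that of the other genes by camera.

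ASCIZ was first described through the DNA damage response, and none of the lists for it passed. In the list of ATM signalling and double-strand break repair, 14 of 19 tested genes were below 0 (median -0.11, camera adjusted p = 0.0706, and adjusted p = 0.519 with an estimated correlation). Rif1, which steers repair of broken ends, passed adjusted over the list alone; it was not well above background on any knockout array and lay at least 1.21-fold lower. The list passed under several alternatives, such as leaving out the XX culture (adjusted p = 0.0340), within a range of 0.0307 to 0.519. Base excision repair (17 tested, median -0.05, smallest p for Parp1 at -0.31), p53 target genes (21 tested, median -0.01, mean 0.01, camera direction upward) and the BCL2 family (14 tested, median 0.09) did not pass and had 0 members past either adjustment. Pmaip1, the proapoptotic NOXA, had the smallest p of both latter lists (0.57, SE 0.22). The proapoptotic BCL2 members Bcl2l11 (0.23, SE 0.35) and Bmf (0.27, SE 0.30, detected on 2 arrays of each genotype), whose products bind the light chains encoded by Dynll1 and Dynll2, differed by less than their errors.

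The remaining lists did not pass. Among signalling lists, cilium assembly (25 tested, median -0.00, top gene Rpgrip1l at -0.27, detected on 2 knockout arrays), Hedgehog targets (11, -0.20) and Wnt targets (13, -0.13) had 0 members past either adjustment, and the cyclin Ccnd1 had the smallest p of both latter lists (-0.41, SE 0.17). In the extracellular matrix list (39 tested, median -0.04), the microfibril protein Mfap5 passed adjusted over the list alone but not over all genes (1.11, SE 0.15, adjusted p = 0.165). Among inflammatory cytokines and chemokines (15, 0.07), the monocyte attractant Ccl7 passed adjusted over the list alone but not over all genes (1.24, SE 0.25, adjusted p = 0.383). Contractile genes of smooth muscle and myofibroblasts (21, 0.03, top gene Cald1 at 0.40), interferon response genes (19, 0.01, Tap1 at -0.38), oxidative stress genes (23, 0.05, Txn1 at 0.32) and unfolded protein response genes (27, 0.00, Atf3 at 0.29) had none. The same held for hypoxia and glycolysis (25, -0.08, Egln3 at 0.29), cytosolic ribosomal proteins (36, 0.01, Rpl3 at 0.23), Hox genes (26, -0.02, Hoxa4 at -0.71) and imprinted growth genes (16, 0.00, Dlk1 at -0.46). Under median scaling, with its shift of -0.18 over all genes, several list means near 0 moved below 0 with that shift, so that only their place against the other genes can be read: there the smooth muscle (adjusted p = 0.0394), inflammatory (0.0362) and cytosolic ribosomal lists (2.84e-05) passed as higher, within ranges over the alternatives that reached 0.982, 0.849 and 0.959. The cytosolic ribosomal list also passed camera as higher with cyclic loess (mean 0.09, adjusted p = 0.0373), where the median of all genes was -0.0016. The extracellular matrix list passed as lower without knockout replicate 3 (mean -0.21 in place of -0.04, adjusted p = 0.00296 within a range of 0.000397 to 0.998), but had a mean of 0.08 without knockout replicate 1 and 0.03 without wild-type replicate 2. Without the XX culture and knockout replicate 3 it passed too (mean -0.27), and the interferon list turned from a mean of 0.06 to -0.17 (adjusted p = 0.0422 within a range of 0.0422 to 0.998). In that setting Wnt targets (mean -0.24, adjusted p = 0.0422 within a range of 0.0422 to 0.998) and the inflammatory list (mean 0.23, adjusted p = 0.0422) also passed. Hox genes passed without knockout replicate 2 (mean -0.23, adjusted p = 0.0325 within a range of 0.0325 to 0.982). In these lists the first number is the count of tested members and the next the median log2 fold change.

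The genes around Atmin on chromosome 8 showed no shift: 21 were tested, 11 above and 10 below 0, with a median of 0.06, a mean of 0.01 and a camera direction that was downward (adjusted p = 0.962), and upward under median scaling. None passed over all genes or adjusted over the list alone, and Adamts18, detected on 1 wild-type and all 3 knockout arrays, had the smallest p (0.65, SE 0.23). The 4 tested sex-linked genes were higher in the knockout cultures by 0.07 to 1.63 and did not pass (adjusted p = 0.131). They passed under median scaling (adjusted p = 0.000362), without wild-type replicate 2 (0.0121) and without wild-type replicate 3 (0.0481), within a range of 0.000362 to 0.896. Ddx3y (1.63, SE 1.18), Eif2s3y (1.53, SE 1.05) and Kdm5d (0.75, SE 0.42) were measured with the XX culture in the wild-type group, and without it Ddx3y stood at 0.03; Uty differed by 0.07 (SE 0.15), turning to -0.02 under median scaling.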

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

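Probes whose array name matched no gene in the reference table took no part in the gene test. When all 18221 detected probes were tested one by one, 1 of these unnamed probes, carried on the array as LOC100040479, stood above the wild-type level. It was not well above background on any wild-type array and was detected on all 3 knockout arrays, with means of 4.35 ± 0.08 and 6.78 ± 0.41 (SD, n = 3 each), a fitted log2 difference of 2.42 (adjusted p = 0.00776 by limma) and a bound of at least 3.94-fold higher. Its gene is not named here, and no explanation was tested.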

How the results depend on the processing

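Culture sex, the array's own names and leaving out 2 cultures together were chosen after the data were seen; as 1 culture was XX, culture sex gives the same fit as leaving out wild-type replicate 1. In place of 5 genes, 3 passed with an offset of 50 and no negative controls, without a filter on dim probes (20611 genes tested), at an adjusted p under 0.01 and against a 1.2-fold change; 2 passed without background correction, in the submitters' values and with the replicate number as a block; 1 passed with ordinary least squares and with culture sex as a covariate. Of single probes 8 passed, and with array weights 9 genes. Leaving out 1 array gave 1 to 4 genes, fewest without wild-type replicate 1 or 3. Atmin kept its direction and lost its call averaged over probes (-1.28), with ordinary least squares (-1.99), with the replicate block (-1.99, adjusted p = 0.0580) and with culture sex (-2.03); with 1 array left out it ranged from -2.08 to -1.84. In place of 6 lists, 12 passed under median scaling (7 higher, 5 lower), 12 without the XX culture and knockout replicate 3, 0 with an estimated correlation and 1 with either fry test. Apart from the estimated correlation, fewer arrays, fewer degrees of freedom and more genes tested, the cause was not tested. No pairing by replicate number was seen: deviations of same-numbered cultures correlated at 0.23, -0.18 and -0.20, and other pairs at -0.33 to 0.40. So few cultures cannot exclude a pairing. The block ended the calls of Atmin and 2 other genes. Of single genes that turned sign none had passed: Dynll2 under median scaling (-0.16) and without both cultures (-0.011), with 1 array left out from -0.011 to 0.16; Uty under median scaling (-0.024), array weights (-0.042), culture sex (-0.0083) and without both cultures (-0.040), with 1 array left out from -0.017 to 0.20; and Ddx3y without both cultures (-0.018), with 1 array left out from 0.032 to 2.50. The mean of the oxidative phosphorylation list, which had passed, followed the shift of all genes under median scaling to -0.03 and camera kept its direction. The interferon list, which had not passed, turned to -0.17 without both cultures (adjusted p = 0.0422). Apart from Atmin, Dynll1 and the counts, 1551 values of single genes and lists were counted as unchanged. Of the rest 58 lost and 31 gained a call, and 11 turned sign. For lists, direction was checked only where the list passed with the main processing or in the alternative. Lists that passed in neither were counted as unchanged even where they turned. Cilium assembly, for example, went from a downward to an upward camera direction with an offset of 50 and no negative controls. No slide was named in the files, so a slide block was not run. Dim signal limits the rest: 18221 of 45281 probes exceeded background on at least 3 arrays.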

Other observations

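Several genes differed widely without passing, and are named here after their values were seen. Sprr2k, a small proline-rich protein of barrier epithelia, was higher in the knockout cultures by 2.56 (SE 0.43, adjusted p = 0.266) and passed without wild-type replicate 2 (1.99), and Klra4, a natural killer cell receptor gene, was lower by a log2 fold change of -2.03 (SE 0.42, adjusted p = 0.383). Of the X-linked Bex and Tceal genes, Bex4 had 1.10 (SE 0.22), Tceal7 1.03 (SE 0.17) and Tceal5 0.80 (SE 0.14), while Bex1 (-0.20, SE 0.17) and Tceal3 (-0.22, SE 0.17) lay below 0; none passed, and the families were not tested as groups.

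The tests of the 3 patterns weighed next that used the XX culture, the opposing lists or chromosomes were chosen after the results were seen; those on held-out genes, on neighbouring genes and on other splits were set beforehand, and the count without gene families was added later. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, called as many as 5 genes, and the highest other split called 0. As many as 6 lists were called by 4 of the 10 splits, the real one included, and the highest other split called 7. So few splits cannot give a share under 0.05 for either count. At an unadjusted p under 0.05 the split of wild-type replicates 1 and 3 with knockout replicate 1 against the rest gave 1115 genes, against 854 for the real split.

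The lower macrophage markers in the knockout cultures did not come from the XX culture alone. That culture had the lowest wild-type mean of the list (6.31, against 7.04 and 6.66 in wild-type replicates 2 and 3). Leaving it out could therefore only enlarge the shift, which lay at -1.14 (SE 0.21) without it. A larger wild-type share of all cells other than fibroblasts would have lowered the muscle markers too in knockout cultures, and these lay higher by 0.68 (SE 0.23). Fewer macrophages may be a source, but the 15 of 51 held-out macrophage genes that were tested lay at -0.22 (SE 0.08), short of the -0.5 set beforehand, with 9 below and 6 above 0, and did not pass camera (adjusted p = 0.0951, and adjusted p = 0.188 with an estimated correlation). Among these genes Trem2, Ccl4 and Ms4a6d were detected on all 3 wild-type arrays and no knockout array (bounds of at least 1.15-fold to 1.52-fold lower) and Ccl9 had -0.79, while Lst1 (0.31), Tlr13 (0.15) and Coro1a (-0.08), dim as well, were not lower or hardly so, and Gpnmb, Lgals3, Arhgdib and Cyba are abundant in these cultures as a whole, above 11 on the log2 scale, and would hide a small share. A change in macrophage number and a change within macrophages cannot be told apart here because the held-out genes went both ways, and a role of ASCIZ was not tested.

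The higher skeletal muscle markers may reflect more muscle cells in the knockout cultures, because 21 of 58 held-out muscle genes were tested and lay 0.27 higher (SE 0.12), 16 above and 5 below 0, from Mb (1.08) to Mustn1 (-0.73); this fell short of the 0.3 set beforehand. That list passed camera (adjusted p = 9.52e-05, but adjusted p = 0.188 with an estimated correlation), so the question stays open. The XX culture had the lowest values, and without it the list still lay at 0.51 (SE 0.20). A lower fibroblast share in the knockout cultures would have raised macrophage markers as well, which lay at -0.96 (SE 0.24). More muscle cells, a change within them and differences in dissection between embryos cannot be told apart with so few held-out genes above background.

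Fmr1nb, Gal3st1 and Got1l1 stayed higher in the knockout cultures when the XX culture was left out. The smallest of the 3 log2 fold changes, that of Gal3st1, was then 1.13 (SE 0.14) in place of 1.17 (SE 0.11). With fewer arrays none of the 3 passed (adjusted p from 0.0810 to 0.226 by limma). The 3 genes were picked because they had passed, which favours a small spread within groups. This check could thus hardly have come out otherwise, and no verdict on the XX culture is drawn from it. Passenger DNA beside the targeted locus is argued against by position, since 2 of the 3 genes lie on other chromosomes than Atmin; Got1l1 lies on chromosome 8 as Atmin does, but is not among the 34 listed neighbours of Atmin, so that for it a segment reaching beyond these was not tested. A general release of germline genes was a candidate explanation because Fmr1nb and Got1l1 are known for expression in testis: 13 of 101 germline genes were tested and lay at 0.074 (SE 0.088). Of 154 germline probes 0 were detected on all knockout and no wild-type arrays. Over all 45281 probes there were 34, so about 0 was to be seen by chance too and the count decides nothing. Genes past the threshold had been left out of the germline genes, so Fmr1nb is among the 34 and could not be among the 154. Most germline genes lay near or below background, so a release stays open.

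Passenger segments elsewhere in the genome might show as neighbouring genes among those with the smallest p. Of the top 100 genes, 17 had another of them within 5 tested genes on their chromosome, against a median of 8 and an upper 95% bound of 16 in 10000 random draws (permutation p = 0.0319, one-sided), which met the rule set beforehand. Without pairs from a single gene family, such as Lyz1 and Lyz2, a count chosen after the pairs were seen, 10 remained (permutation p = 0.434, one-sided). Linkage and shared regulation of related genes cannot be told apart with these arrays, since family members lie side by side.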
